A study of Mus musculus with 18 samples.

How the data were processed

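The series holds 18 samples of mouse embryonic stem cells, wild type or Tet2 KO. Per the labels' protocols, cells were grown with LIF on fibroblast feeders, and poly(A) RNA was selected and then depleted of ribosomal RNA. Fragmented RNA was bisulfite converted with an RNA methylation kit for the bisulfite libraries, and actinomycin D was given at 5 µg/ml for the turnover libraries. Groups, replicate numbers and times were taken from the sample titles. Comparisons used 4 bisulfite samples, 2 per genotype, and 6 RNA-seq libraries, 1 per genotype and time (0, 3 and 6 h). The 8 m5C immunoprecipitation and input samples were not used here.

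The RNA table holds RPKM values per locus that the authors deposited, per the file headers. The header of the wild type 0 h column lacks the first letter of that unit and was read as the same unit. The 2 site tables hold, per the file headers, the deposited m5C level of each site in each replicate as a fraction, with chromosome, position, strand and gene. Neither table gives coverage. The lowest level listed in either replicate was 0.1, so a position not listed may have been below that level or not covered. Per the submitters' processing notes, Trimmomatic, Bowtie2, Cufflinks and MACS2 were among the tools used and the builds were mm10 and GRCm38. Their versions and roles are not given in the sources used here. Duplicate handling, strand use, the treatment of multiply mapped reads and the rule by which a site was listed are not given either, and each could change a level or an RPKM. RNA that resists conversion, or that is read from DNA, would count as m5C in any such assay, and no spiked or unmethylated control was used here.

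RPKM were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), after keeping loci with a mean RPKM of at least 1, with empirical Bayes moderation, a mean trend and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low loci. The genotype contrast had time as a block (2 residual degrees of freedom), the time contrast fitted a slope per hour with genotype as a factor (3), and the slope difference was the interaction (2). Of the loci tested, 742 carry several symbols, from overlapping genes. They stayed in the counts and out of the gene lists. Tests were two-sided. RPKM cannot show absolute decay, because each library is scaled to its own total, so slopes are changes relative to the library.

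Gene lists, 24 in all, were fixed with the designs and the naming rule before the data were examined. They cover pluripotency, formative and primed pluripotency, neural ectoderm, mesoderm, endoderm, trophectoderm, two-cell-like, germline, methylation machinery, fibroblast feeder, p53 target, immediate early, interferon, amino acid stress, sterol synthesis, glycolysis, imprinted, noncoding host, ribosomal protein, oxidative phosphorylation, proteasome, histone, Zfp zinc finger and mitochondrially encoded genes. The 19 lists with at least 5 tested members went into camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. A set of S-phase genes was fixed later, for 1 test of the closing section, where X-linked, Y-linked and small structured RNA loci were taken from the RefSeq table. The naming rule took Tet2 always, the 12 largest changes in each direction among loci that passed with the same direction at every time or in both genotypes, or the 10 smallest p values where fewer than 5 passed, and the 4 members of smallest p from each list. For sites it took the 10 widest differences among shared sites, the 5 highest levels per table and sites in the pluripotency, methylation machinery and two-cell-like lists. Pseudogenes and unplaced models could be left unnamed, and some single-gene results that the rule names are not reported here.

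Sites were matched between tables by chromosome, position and strand. Shares carry 95% exact (Clopper-Pearson) binomial intervals over sites, which cover counting of sites and not the error of each level. Without coverage no count test per site was possible, so levels were compared by differences, by an exact binomial test over sites and, added later, by limma on arcsine square root levels. Gene positions and classes came from a RefSeq table of GRCm38.p6, which gives no exons, so exon, intron and UTR positions and the sequence context of sites were not analysed here. It gives no strand either. Sites were therefore placed in genes by position alone, and where genes overlapped a protein-coding gene was taken before others. For the genes with sites, medians were ranked among 10000 random lists matched on mean expression in 20 bins.

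The relative depth of the RNA-seq libraries was estimated from loci under 0.3 RPKM. Where whole reads are counted, the ratio of such a value between libraries is a ratio of small whole numbers times 1 constant per pair of libraries. Within a tolerance of 0.002 on the natural log scale and with at most 8 reads, between 11.0% and 44.8% of ratios were of this kind, against 3.45% at other constants, so only part of the values behave as whole reads and no read counts were derived.

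The tests across genes or sites were run on simulated data. With 200 of 11855 loci changed by a log2 value of 1, limma called 0% in the genotype, time and interaction contrasts, and at a log2 value of 2 it called 53%, 55% and 0%. For shared sites it called 63.5% of 200 sites shifted by 0.3 on the arcsine scale. With noise independent between genes, camera with the preset correlation called a histone list of 33 genes that fell by a log2 value of 1 in each contrast (adjusted p = 3.48e-11, 2.26e-05 and 6.12e-06) and none of 18 other lists. With an estimated correlation it missed that list even at a fall of 4 (0.362, 0.0739 and 0.138), so a call lost with the estimated correlation does not show that a list did not change. The binomial test over 1039 sites passed in 6 of 100 draws without a shift and in 100 with a shift of 0.02. Bootstrap intervals held the true value in 94 of 100 draws for a list of 20, a list of 200 and a difference of 2 medians each. Those draws were of independent values. The intervals resample genes, which may vary together, and hold no error between libraries or cultures. The percentile of a random list of 500 genes was 45.2, and 100.0 after a shift of 0.2. Alternatives covered pseudocounts of 0.1 and 0.5, no filter or a mean RPKM of at least 5, quantile normalization, scaling to ribosomal protein and oxidative phosphorylation genes, no trend, no time block, times or libraries left out, loci of a single symbol, higher minimum levels and replicates left out. The slope in each genotype was planned as a value and was also tested, with 1 residual degree of freedom. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.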

Results

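The series profiled RNA 5-methylcytosine (m5C) and RNA turnover in mouse embryonic stem cells, cultured with LIF on mouse embryonic fibroblast feeders, that were wild type or carried a knockout of Tet2. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine. Values were used from 10 of the 18 samples. RNA bisulfite sequencing, in which an unconverted cytosine is read as m5C, gave 2 replicates per genotype. RNA sequencing gave 1 library per genotype at 0, 3 and 6 h of actinomycin D, a drug that blocks transcription, at 5 µg/ml. The 8 m5C immunoprecipitation and input samples were not used here. Nothing in the labels says that replicates came from separate cultures. The limma p-values below therefore measure only the spread between these samples, which may be technical. The camera p-values compare listed genes with other genes, and the exact binomial p-values count sites, so neither measures a spread between cultures.

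The RNA table listed 14864 loci, all above 0 RPKM in the 6 libraries, and 11855 of them had a mean RPKM of at least 1 and were tested. The median RPKM was 5.48, 4.64 and 3.43 at 0, 3 and 6 h in wild type and 5.31, 4.56 and 3.57 in Tet2 KO. The 10 highest loci held between 37.2% and 43.0% of the summed RPKM of a library. Numbers of reads were not given. Relative depth, read from the ratios of low RPKM values, was lowest in the Tet2 KO 3 h library. Set to 1.00 there, it was 1.31 in Tet2 KO 0 h, 1.77 in Tet2 KO 6 h, 1.78 in wild type 3 h and 1.73 in wild type 6 h. For wild type 0 h it was not settled, with 2.27 in the best solution and 1.14 in the next. The depth behind each bisulfite level is unknown, because the site tables gave levels without coverage.

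Tet2 RNA itself was present in every library. Its RPKM was 23.7, 17.9 and 12.5 in wild type at 0, 3 and 6 h, and 23.0, 11.2 and 10.1 in the libraries labelled Tet2 KO. The genotype difference was -0.32 on the log2(RPKM + 1) scale (SE 0.20, limma adjusted p = 0.593). RNA level therefore did not separate the genotypes at this gene. The labels do not say which part of Tet2 was deleted, and a gene-level RPKM also counts the parts that remain. Directions between the genotypes below rest on the labels.

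The first comparison asked which RNAs differed in level between the genotypes over the 3 times. The strongest increase in the libraries labelled Tet2 KO was that of Peg3, a paternally expressed imprinted gene encoding a zinc finger protein. Its RPKM was 4.31, 4.37 and 3.19 in wild type against 56.5, 49.9 and 51.6 in Tet2 KO. On the scale of RPKM + 1 this was a 10.9-fold difference (log2 difference 3.44, SE 0.18, limma adjusted p = 0.0121), which understates the fold of the RPKM themselves. Zfp42, also called Rex1 and a marker of naive pluripotency, went down from 120, 52.5 and 24.7 to 30.6, 10.8 and 6.79 RPKM (-1.95, SE 0.18, adjusted p = 0.0434). Fmr1nb, an X-linked gene beside Fmr1, went down from 18.4, 21.5 and 14.9 to 1.25, 2.19 and 1.98 RPKM (-2.78, SE 0.23, adjusted p = 0.0323). The other 6 calls are pseudogenes, Rpl34 pseudogenes among them, and unnamed gene models, all lower in Tet2 KO, with log2 differences between -3.68 and -1.85. They are uncertain where their reads could be shared with near-identical genes, and Rpl34 itself differed by 0.49 (adjusted p = 0.390).

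In all, 9 of 11855 loci passed at an adjusted p under 0.05 with time as a block, 1 higher and 8 lower in Tet2 KO, and each moved the same way at all 3 times. At an unadjusted p under 0.05 there were 1285. With quantile normalization 3 passed, 1 higher and 2 lower, without the trend 5, 1 higher and 4 lower, without a filter on low values 4, and at a mean RPKM of at least 5 there were 15. Peg3 passed in each of these settings, while Fmr1nb (adjusted p = 0.0814) and Zfp42 (0.0814) missed the threshold with quantile normalization and without the filter (0.0734 each), and Zfp42 without the trend (0.0823) or the time block (0.796). Peg3, Zfp42 and Fmr1nb all missed it, with 0 calls in all, without wild type 3 h, wild type 6 h, Tet2 KO 3 h or Tet2 KO 6 h. There were 7 calls without wild type 0 h, where Fmr1nb (0.0504) and Zfp42 (0.0670) missed it, and 12 without Tet2 KO 0 h, where Zfp42 did (0.0552). With time as a block, the library left alone at a time adds nothing to the genotype difference. The median over all loci was 0.0691 without either 3 h library and without the 3 h pair. Here and for the gene lists below, leaving out wild type or Tet2 KO of the same time is therefore not 2 separate checks.

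**Figure D1:**
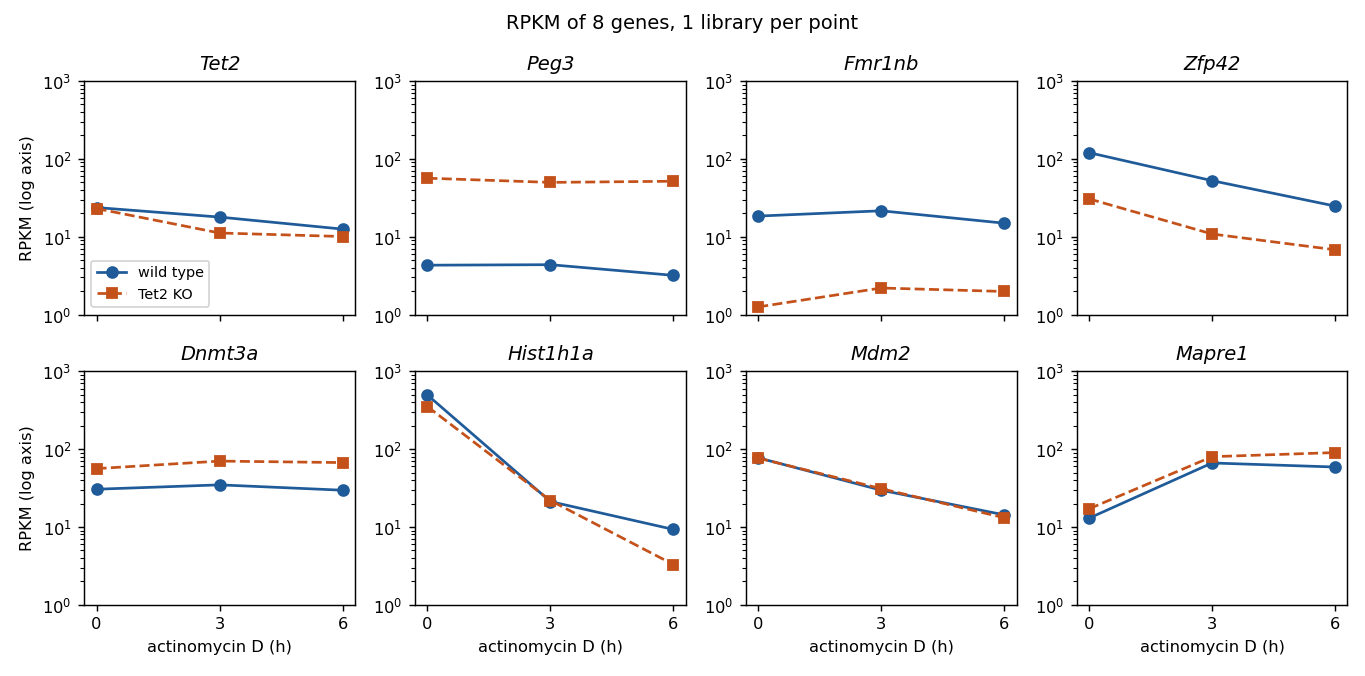
RPKM on a log axis against hours of actinomycin D for Tet2, Peg3, Fmr1nb, Zfp42, Dnmt3a, Hist1h1a, Mdm2 and Mapre1, with 1 library per point, wild type as circles and Tet2 KO as squares. Peg3 was at 56.5, 49.9 and 51.6 RPKM in Tet2 KO, above 4.31, 4.37 and 3.19 in wild type, while Zfp42 and Fmr1nb lay lower in Tet2 KO at each time.

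Among genes with known roles in these cells, Dnmt3a, a de novo DNA methyltransferase, had a log2 difference of 1.00 (SE 0.16) and Lin28a, an RNA-binding protein of stem cells, one of 0.67 (SE 0.15). Neither passed (adjusted p = 0.162 and 0.309). Of 22 pluripotency genes tested, Zfp42 alone was called over all genes and also adjusted over the list alone, 15 were higher and 7 lower, and the median and the test pointed up (camera adjusted p = 0.556). The formative and primed pluripotency list had 5 of 7 genes higher (adjusted p = 0.256), and the DNA and RNA methylation machinery 10 of 13 (0.148). Dnmt3a was the member that passed when adjusted over either list alone, 1 gene in each. Markers of the fibroblast feeders had a median difference of -0.09 over 18 genes (adjusted p = 0.256).

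Replication-dependent histone genes were the lowest group in Tet2 KO: 32 of 33 were lower, with a median log2 difference of -0.96. In the same libraries 218 small structured RNA loci, which like these histone mRNAs lack a poly(A) tail, had a median of -0.448 (bootstrap interval -0.509 to -0.398). No histone gene passed over all genes, and 2 passed adjusted over the list alone. Hist1h2bq and Hist1h2bl differed by -0.96 and -0.97, and Hist1h4b and Hist1h2ab by -1.35 and -1.15 (adjusted p between 0.252 and 0.333). The camera test with its preset correlation called the list lower (adjusted p = 9.95e-15), but not with an estimated correlation (adjusted p = 0.622). The direction of the median was the same under each scaling, and leaving out any 1 library did not end the call.

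Among the other lists, 7 of 7 endoderm markers were lower (median -0.40), among them Cubn, an endocytic receptor, at -0.83, and Col4a1, a basement membrane collagen, at -0.51. The list was called lower (adjusted p = 0.00833), but not with an estimated correlation (adjusted p = 0.622), nor without wild type 3 h (0.0594) or Tet2 KO 3 h (0.0570). Fibroblasts also express collagen IV, and of 11 feeder markers less shared with stem cells, a subset chosen after the data were seen, 9 were lower (median -0.127, bootstrap interval -0.346 to -0.0738), while 6 Y-linked loci, 4 of them lower, had a median of -0.614. Imprinted genes were called higher (adjusted p = 0.00833, and adjusted p = 0.622 with an estimated correlation), with 8 of 12 higher, Peg3 called over all genes and 3 genes adjusted over the list alone. The other two were Phlda2 at 1.00 and Mest at 0.89, which did not pass over all genes. The imprinted call ended without wild type 6 h (0.0502) or Tet2 KO 6 h (0.0522), and with loci of several symbols as members (0.443). Proteasome subunits were called higher (29 of 34, median 0.21, adjusted p = 0.00833, and adjusted p = 0.810 with an estimated correlation), with the immunoproteasome subunit Psmb8 at 1.27 and the ATPase subunit Psmc1 at 0.54. That call ended without wild type 6 h (0.0765) or Tet2 KO 6 h (0.0766).

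Sterol synthesis genes were higher in 10 of 11 cases (median 0.39, adjusted p = 0.0128), with Idi1 at 0.84 and Hmgcs1 at 0.41. The call was not kept with an estimated correlation (adjusted p = 0.622), nor without wild type 3 h (0.0753), Tet2 KO 3 h (0.0768) or Tet2 KO 0 h (0.0507). All 5 neural ectoderm markers were higher (median 0.34, adjusted p = 0.0309), with Stmn2 at 0.97 and Pax6 at 0.67. That call was not kept with an estimated correlation (adjusted p = 0.622), nor without wild type 0 h (0.0516), Tet2 KO 0 h (0.0507), wild type 3 h (0.264) or Tet2 KO 3 h (0.264). Adjusted over the list alone, Idi1 passed in the sterol list and Stmn2 in the neural list. Ribosomal proteins (adjusted p = 0.0600), germline genes (0.119), p53 targets (0.195), glycolysis (0.195), oxidative phosphorylation (0.502), immediate early genes (0.503, with a median of 0.05 against a test that pointed down), amino acid stress genes (0.556), Zfp zinc finger genes (0.556) and interferon genes (0.687) did not pass. The ribosomal list was lower by the test when scaled to ribosomal protein and oxidative phosphorylation genes, which makes its own members part of the reference (0.00300), or without wild type 6 h (0.0201) or Tet2 KO 6 h (0.0215), and did not pass with an estimated correlation (adjusted p = 0.810). No member of the mesoderm, two-cell-like, noncoding host and mitochondrially encoded lists was tested as a locus of a single symbol. For noncoding hosts, 6 tested loci of several symbols held a member. The 2 trophectoderm markers, too few for a test, had a median of -0.23.

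The second comparison asked how relative RNA levels changed during actinomycin D, fitted as a slope per hour over both genotypes. Histone RNAs declined most: 31 of 33 passed, all 33 passed adjusted over the list alone, and the median slope was -0.66 log2 units per h. These mRNAs lack a poly(A) tail, and the libraries were poly(A) selected. How much of them passed the selection may differ between libraries, which was not tested, so their slopes cannot be read as turnover alone. The linker histone genes Hist1h1a and Hist1h1b fell by 1.00 (SE 0.10, adjusted p = 0.00725) and 0.92 per h, and the core histone genes Hist1h2bb, Hist1h3a and Hist1h3b by 0.85, 0.83 and 0.82. Of 11 immediate early genes, 5 fell, among them Dusp6, a phosphatase of ERK, with a slope of -0.68, and Egr1 and Klf10 with -0.39 and -0.40. Of 16 p53 targets, 8 fell, including Mdm2, the ubiquitin ligase of p53, with -0.40, Plk2 with -0.52 and Cdkn1a, the cell cycle inhibitor p21, with -0.36. Of 22 pluripotency genes, 7 fell, among them Socs3, a feedback inhibitor of LIF signalling, with -0.63, Klf2 with -0.50, Klf5 with -0.35 and Zfp42 with -0.35. With quantile normalization, 2 histone, 1 immediate early, 3 p53 target and 2 pluripotency genes passed, while the list medians relative to all loci were -0.62, -0.25, -0.17 and -0.10. With scaling to ribosomal protein and oxidative phosphorylation genes, 3 immediate early genes passed.

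In all, 952 of 11855 loci passed, 14 rising and 938 falling relative to the library as a whole, and 2820 had an unadjusted p under 0.05. Mapre1, a protein of growing microtubule ends, rose with 0.37 per h (SE 0.08, adjusted p = 0.0357), Exd2, an exonuclease, with 0.30, Camta1 with 0.26, Wdr25 with 0.26, Ebf1, a transcription factor of B cells, with 0.24 and Hormad2, a meiotic chromosome protein, with 0.23. RPKM are relative within a library, and the median slope of all tested loci was -0.05 per h. Quantile normalization moved that median to 0.02, and scaling to ribosomal protein and oxidative phosphorylation genes moved it to -0.08. Tet2 had a slope of -0.17 (adjusted p = 0.0603). With quantile normalization 114 loci passed, 5 rising and 109 falling. Leaving out wild type 6 h gave 0 calls, wild type 0 h 113, Tet2 KO 0 h 176, wild type 3 h 217 and Tet2 KO 3 h 1476. At 3 h against 0 h alone 9 loci passed, at 6 h against 0 h alone 580, and in Tet2 KO alone 0 passed, against 1262 at an unadjusted p under 0.05.

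Relative to the median of all loci, the histone list had a median slope of -0.62, immediate early genes -0.26, p53 targets -0.16, Zfp zinc finger genes -0.13 and pluripotency genes -0.09. Each kept its sign under both other scalings, and the calls held whichever 1 library was left out. The preset adjusted p values were 2.66e-21, 8.79e-06, 0.000140, 1.05e-12 and 0.000968 in that order, and the adjusted p was 0.596 for each of the 5 with an estimated correlation. Of 182 Zfp genes, 49 fell, with 104 adjusted over the list alone and 3 over all genes with quantile normalization, among them Zfp958 with -0.50, Zfp141 with -0.39 and Zfp622 with -0.28. Adjusted over the list alone, 10 immediate early genes, 9 p53 targets and 12 pluripotency genes passed. Jund fell with a slope of -0.23 and Sesn2, a stress-induced p53 target, with -0.39.

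The other side of the ranking held lists that were stable relative to other loci, with medians above that of all loci by 0.07 for oxidative phosphorylation, 0.06 for ribosomal proteins, 0.05 for fibroblast feeder markers and 0.04 for proteasome subunits. With the preset correlation these 4 were called higher (adjusted p = 3.06e-06, 5.22e-06, 0.00256 and 0.00876), and with an estimated correlation they were not (adjusted p = 0.611, 0.611, 0.611 and 0.689). Of their members Ndufa10, a subunit of respiratory complex I, fell with a slope of -0.27, as the 1 gene of its list that passed over all genes or adjusted over the list alone, though not with quantile normalization, and no gene of the other 3 lists passed. The median slopes of the oxidative phosphorylation, ribosomal and feeder lists were 0.02, 0.01 and 0.01 as deposited. That of the proteasome was -0.00, above the -0.05 of all loci, with which the test compares a list. Scaling to ribosomal protein and oxidative phosphorylation genes takes 2 of these lists as its reference, and the medians of the 4 lists relative to all loci were then 0.06, 0.06, 0.05 and 0.04. With quantile normalization the ribosomal list turned lower (adjusted p = 0.325) and the proteasome call ended (0.102), as it did when scaled (0.420). Without Tet2 KO 0 h none of the 4 passed (adjusted p = 0.0567, 0.0743, 0.0523 and 0.30 in the order above).

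Some members fell in lists that did not pass as groups. In sterol synthesis Msmo1, a sterol oxidase, fell with -0.26 (list adjusted p = 0.0867 over 11 genes, 5 of which passed adjusted over the list alone). In the formative list 2 of 7 fell, Tcf15 with -0.44 and Sox4 with -0.25 (0.276, 3 adjusted over the list alone). In the amino acid stress list 2 of 12 fell, the transcription factor Atf4 with -0.44 and Trib3 with -0.42 (0.665). Irf1 with -0.45 was the 1 of 9 interferon genes that fell (0.711), and Slc2a1, a glucose transporter, with -0.35 the 1 of 14 glycolysis genes (0.997). With quantile normalization no sterol or formative gene and 1 amino acid stress gene passed. No endoderm or germline gene (both 0.0597), methylation machinery gene (0.253), imprinted gene (0.456) or neural ectoderm gene (0.509) passed. The endoderm list was called higher than other loci with quantile normalization (0.0222), when scaled (0.0398) and without wild type 6 h (0.0322), and the germline list with quantile normalization (0.0269), when scaled (0.0398) and without Tet2 KO 6 h (0.0409). With an estimated correlation neither passed (adjusted p = 0.611 and 0.596). The germline median was -0.00, above the -0.05 of all loci.

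**Figure D2:**
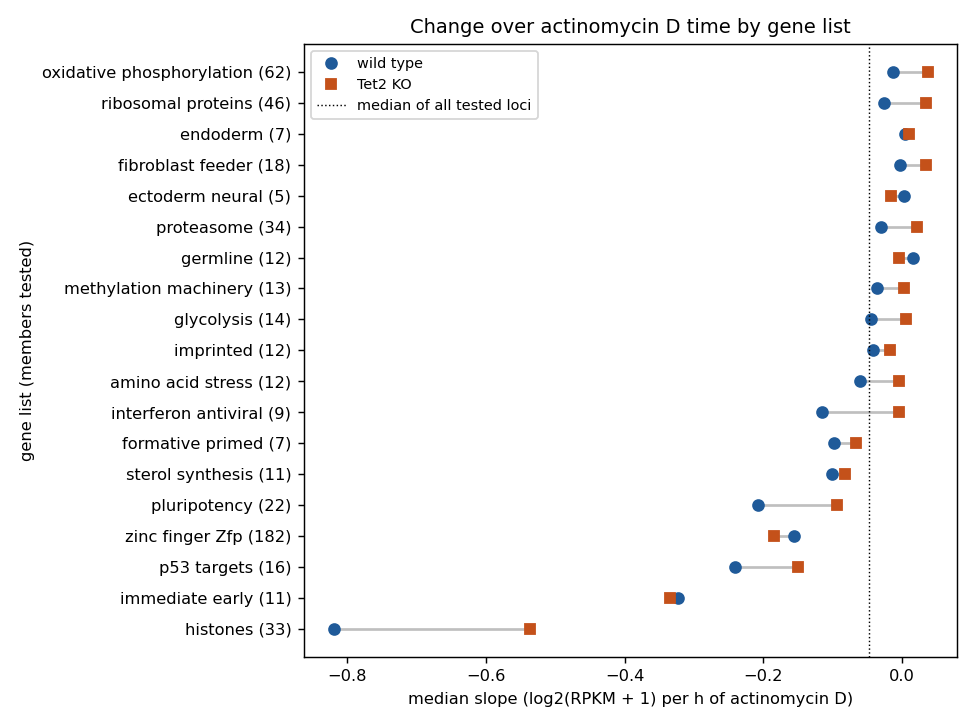
Median slope in log2(RPKM + 1) per h of actinomycin D for each tested gene list, with the number of members tested, in wild type (circles) and Tet2 KO (squares), and the median of all tested loci as a dotted line. Histones lie lowest at -0.82 and -0.54. The ribosomal list turned lower than other loci with quantile normalization.

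The third comparison asked whether RNA declined at a different rate in Tet2 KO, as the difference in slope between the genotypes. Histone RNAs had a median slope of -0.54 per h in Tet2 KO and -0.82 in wild type, and 30 of 33 had a higher slope in Tet2 KO. For these RNAs a difference between libraries in what passed poly(A) selection cannot be told apart from a difference in turnover. Zfp genes had a lower slope in Tet2 KO in 107 of 182 cases, while 42 of 46 ribosomal protein genes and 51 of 62 oxidative phosphorylation genes had a higher one. The median difference of all loci was 0.02 per h. Relative to it, the lists differed by 0.22, -0.04, 0.03 and 0.02 in that order. With the preset correlation all 4 were called (adjusted p = 0.000123, 0.0105, 0.0418 and 0.0418), and with an estimated correlation none was (adjusted p = 0.955 for each). With quantile normalization 30 of 33 histone, 21 of 46 ribosomal protein and 31 of 62 oxidative phosphorylation genes had a higher slope in Tet2 KO and 116 of 182 Zfp genes a lower one. No member passed, over all genes or adjusted over the list alone.

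These 4 list calls depended on single libraries, and all but the histone call depended on the scaling. The histone difference turned lower in Tet2 KO without wild type 0 h (adjusted p = 4.00e-13) or Tet2 KO 6 h (5.92e-05). The Zfp list reversed without wild type 6 h (0.125) or Tet2 KO 0 h (0.377) and missed the threshold without Tet2 KO 3 h (0.0530). Oxidative phosphorylation reversed without wild type 6 h (0.925) or Tet2 KO 0 h (0.803) and missed it without Tet2 KO 3 h (0.538). Ribosomal proteins reversed without Tet2 KO 0 h (0.803) and missed it without wild type 6 h (0.925), Tet2 KO 3 h (0.566) or Tet2 KO 6 h (0.127). With quantile normalization the adjusted p was 0.109 for Zfp genes, 0.880 for oxidative phosphorylation and 0.659 for ribosomal proteins, whose median difference turned to -0.00. With loci of several symbols as members both of the last lists missed it (0.0695). The other 15 lists had adjusted p values of 0.520 or more, and of these immediate early genes passed in opposite directions, lower without wild type 0 h (3.90e-06) or Tet2 KO 6 h (0.00389) and higher without wild type 6 h (0.000193) or Tet2 KO 0 h (0.0256). Proteasome (0.000426), feeder (0.00865) and glycolysis genes (0.0361) passed as higher without wild type 0 h. With all 6 libraries and an estimated correlation none of these lists passed (adjusted p = 0.955 for each).

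For single genes limma made 0 calls on the slope difference, with 488 loci at an unadjusted p under 0.05. The 10 genes of smallest p, none of which passed (adjusted p = 1.00 for each), were Fibp with a difference of 0.63 per h (SE 0.12), Mier2 with 0.57, Ptpru with 0.55, Coa7 with 0.54, the chemokine Cxcl10 with 0.54, Scarna17 with 0.52, Fmn2 with 0.50, Clptm1l with 0.50, Zfp382 with -0.53 and Cfap69 with -0.56. Tet2 differed by -0.04 (SE 0.10), and by 0.10 without Tet2 KO 0 h. With 1 residual degree of freedom, leaving out Tet2 KO 0 h, 3 h or 6 h gave 293, 177 and 263 calls, and leaving out any wild type library gave 0. Simulated slope differences that sum to a log2 change of 2 were called in 0% of genes, so the count of 0 does not show equal rates. More loci passed for the slope in wild type alone (1378) than in Tet2 KO alone (0), but the difference itself was the test with 0 calls.

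The bisulfite tables listed 4128 m5C sites in wild type and 4781 in Tet2 KO, each with a level of at least 0.1 in both replicates. They fell in 2881 and 3237 genes, and 93.5% and 92.4% of the sites lay in a protein-coding gene. Genes were assigned by position without strand, with protein-coding genes taken first, so these shares may include sites of antisense or noncoding RNA. Only 1039 positions were in both tables, 25.2% of the wild-type sites (95% exact interval 23.9% to 26.5%) and 21.7% of the Tet2 KO sites (20.6% to 22.9%). A position missing from a table was not measured as 0. The share in both was greater at higher levels, up to 0.3 to 0.5. Of wild-type sites with a mean level of 0.1 to 0.15, 11.1% were also in the Tet2 KO table, against 74.7% (68.8% to 80.0%) at 0.3 to 0.5. For Tet2 KO sites the shares were 9.68% and 60.3%. At 0.5 to 1 the share was 73.5% for wild-type sites and 60.9% for Tet2 KO sites. At a level of 0.2 or more there were 890, 1134 and 415 sites in wild type, Tet2 KO and both, and at 0.4 or more 146, 215 and 96. By gene, 1526 were in both tables.

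**Figure D3:**
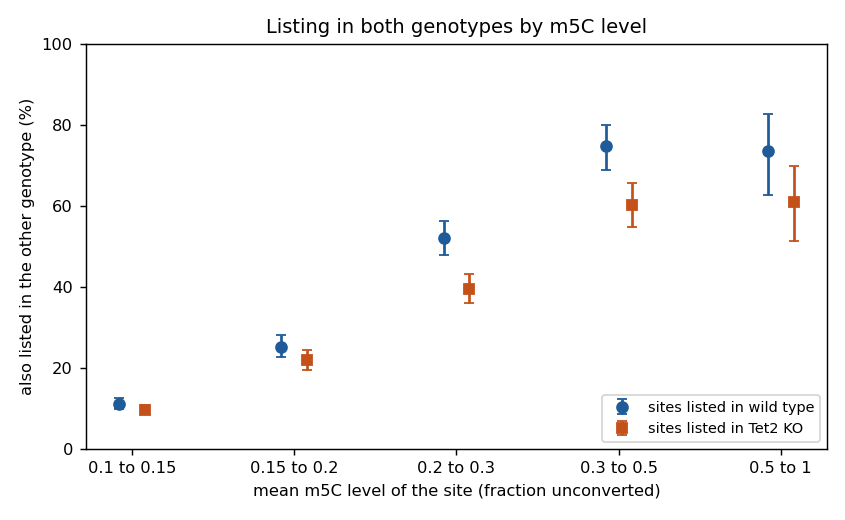
Percent of m5C sites also listed in the other genotype, against the mean level of the site (fraction unconverted), for wild-type sites (circles) and Tet2 KO sites (squares), with 95% exact binomial intervals over sites. For wild-type sites the share is 11.1% at 0.1 to 0.15 and 74.7% at 0.3 to 0.5.

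At the 1039 shared positions the genotypes had nearly equal levels. The median was 0.203 in wild type and 0.204 in Tet2 KO, and the median difference was 0.002. A shared position had to reach 0.1 in every replicate of both genotypes. Sites that a genotype difference moved across that level are therefore left out, which favours equal levels among those that remain. Tet2 KO was higher at 536 sites, lower at 499 and equal at 4, so 51.8% of the unequal sites were higher (48.7% to 54.9%, two-sided exact binomial p = 0.263, with sites as units, which are not replicates). The median absolute difference between replicates was 0.0490 in wild type and 0.0480 in Tet2 KO, against 0.05 to 0.056 between the genotypes. Leaving out wild type replicate 1 raised the share higher in Tet2 KO to 57.5% (exact binomial p = 1.37e-06, median difference 0.01), and leaving out Tet2 KO replicate 1 lowered it to 48.9%. limma on arcsine square root levels, a test chosen after the tables were seen, made 0 calls, with 69 sites at an unadjusted p under 0.05. In 363 sites, 34.9%, the replicates of the genotypes did not overlap, and chance alone gives 33.3%.

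Single positions moved more, in coordinates of mouse build mm10. At Bclaf1, a splicing-associated factor, the site at chromosome 10, position 20322018, had a level of 0.209 ± 0.0587 in wild type and 0.514 ± 0.302 in Tet2 KO (SD, n = 2). At Plxna3, a semaphorin receptor, the site at chromosome X, position 74338361, had 0.340 ± 0.127 and 0.613 ± 0.112. At Rps24, a protein of the small ribosomal subunit, the site at chromosome 14, position 24493560, had 0.160 ± 0.0233 and 0.398 ± 0.0120, and at Cul5, a ubiquitin ligase scaffold, chromosome 9, position 53667154, 0.215 ± 0.00212 and 0.451 ± 0.0269. Bora, Itga9, Ino80, Rnf168 and Klhl26 completed the 9 of the 10 widest differences that were higher in Tet2 KO, and Rlf, at chromosome 4, position 121215001, was lower with 0.744 ± 0.161 against 0.511 ± 0.171. None passed the limma test. A difference of at least 0.1 was seen at 173 sites, 105 higher and 68 lower in Tet2 KO.

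**Figure D4:**
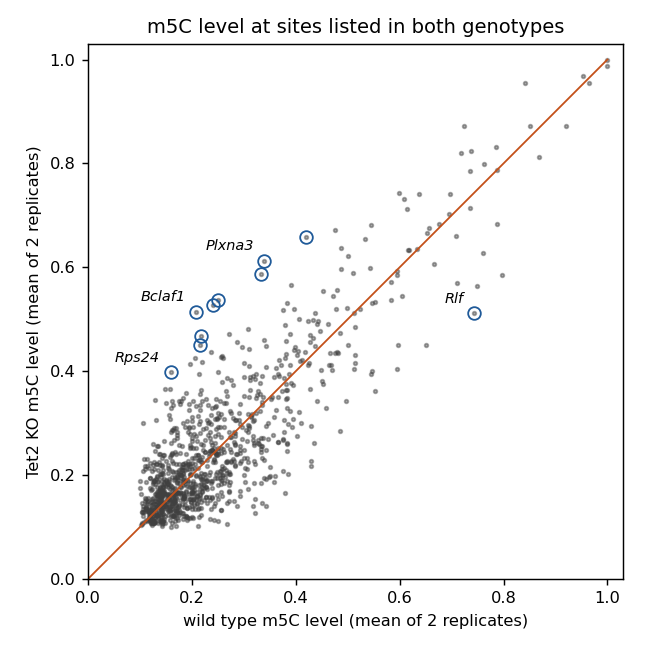
Mean m5C level (fraction unconverted, 2 replicates) in Tet2 KO against wild type for the 1039 positions in both tables, each a point, with the line of equality. Open circles mark the 10 widest differences, 9 of them above the line, and names mark Bclaf1, Plxna3, Rps24 and Rlf.

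Of the sites with a mean level of at least 0.9, 5 of 6 in wild type and 5 of 12 in Tet2 KO were in both tables. Positions in AY036118, a noncoding RNA locus that overlaps a 45S pre-ribosomal RNA repeat (chromosome 17, 39848789), in Tle3, a transcriptional corepressor (chromosome 9, 61417048), in Samd1 and in Nisch had mean levels between 0.953 and 1.00 in wild type and between 0.956 and 0.999 in Tet2 KO. Elk1 (chromosome X, 20950482) was in the wild-type table only (0.925), and Zc3h11a (chromosome 1, 133661178) and Cxxc5 (chromosome 18, 35830072) in the Tet2 KO table only (1.00 each). In the core pluripotency gene Pou5f1 the site at chromosome 17, position 35510397, had 0.461 ± 0.0311 in wild type and 0.491 ± 0.00849 in Tet2 KO. The Nanog site at chromosome 6, position 122713741, had 0.219 ± 0.0205 and 0.343 ± 0.00707. In the DNA methyltransferase genes the levels were 0.257 ± 0.0417 and 0.428 ± 0.0389 at Dnmt3l (chromosome 10, 78056192) and 0.165 ± 0.0354 and 0.291 ± 0.0552 at Dnmt3b (chromosome 2, 153687228), where 2 other shared Dnmt3b positions differed by 0.002 and -0.0490. Over the 9 shared sites placed in 1 gene of the methylation machinery 5 were higher and 4 lower in Tet2 KO, with a median difference of 0.002, and Ybx1 differed by -0.043 and -0.013 and Nop2 by -0.009. Over the 5 shared sites of the pluripotency list 4 were higher and 1 lower, Esrrb with -0.042, with a median difference of 0.03. A Lin28a site (chromosome 4, 134003504) was in the Tet2 KO table only, with 0.519 ± 0.0269. Tet2 held 3 positions in the wild-type table only and 2 in the Tet2 KO table only. The pluripotency list held 15 wild-type and 21 Tet2 KO sites in 12 genes, and the methylation machinery 16 and 21 in 11 genes. No site lay in a gene of the histone, mesoderm, two-cell-like or mitochondrially encoded lists.

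The last comparison joined the tables to ask whether transcripts with m5C sites differed in RNA level or slope between the genotypes. Of the 4592 genes with a site, 87.7% matched a locus of the RNA table. Genes with sites in both tables (1365 tested) had a median level difference at the 50.4th percentile and a median slope difference at the 71.7th percentile of 10000 random lists matched on expression. Genes in the Tet2 KO table only (1371 tested) lay at 57.7 and 92.1, and genes in the wild-type table only (1146 tested) at 1.82 and 69.9. The last group had a median log2 level difference of 0.02, against 0.04 in the random lists. At a mean RPKM of at least 5 its level percentile was 21.8 and its slope percentile 96.1, and for sites of 0.2 or more they were 8.38 and 93.5. For genes in the Tet2 KO table only the slope percentile was 53.2 and 67.3 in these settings, and the level percentile 86.6 and 85.7. With sites of 0.2 or more, genes in both tables lay at 1.47 for level and 97.7 for slope. These percentiles describe the 6 libraries, and genes are not replicates.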

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

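The tests in this part followed the planned design, except that settings with libraries left out or another scaling for the lists, and the counts over other splits of the samples, were chosen after the result was seen. With the preset correlation camera called 4 gene lists for a difference between the genotypes in slope over actinomycin D time, and with an estimated correlation it called none. Histone genes had a higher slope in Tet2 KO (adjusted p = 0.000123, and adjusted p = 0.955 with an estimated correlation), with 30 of 33 genes higher, and turned lower without wild type 0 h (4.00e-13) or Tet2 KO 6 h (5.92e-05). Zfp zinc finger genes had a lower slope (adjusted p = 0.0105, and adjusted p = 0.955 with an estimated correlation), with 107 of 182 lower, which was 0.109 with quantile normalization and reversed without wild type 6 h (0.125) or Tet2 KO 0 h (0.377). Ribosomal protein genes had a higher slope in 42 of 46 cases (adjusted p = 0.0418, adjusted p = 0.955 with an estimated correlation, 0.659 with quantile normalization and 21 of 46 higher, reversed without Tet2 KO 0 h at 0.803). Oxidative phosphorylation genes had a higher slope in 51 of 62 cases (adjusted p = 0.0418, adjusted p = 0.955 with an estimated correlation, 0.880 with quantile normalization and 31 of 62 higher, reversed without wild type 6 h at 0.925 or Tet2 KO 0 h at 0.803).

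Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For the slope difference, 8 of the 10 splits, the real one included, gave at least as many loci at an unadjusted p under 0.05 as the 488 of the real split, and the highest other gave 894. For the genotype comparison 1 split, the real one, gave as many calls, 9, and the highest other gave 5. These splits are of 2 kinds, since 4 of the 10, the real one included, keep 1 library of each time on each side, as the time block needs, and 6 break the pairs. The other 3 that keep the pairs gave 0 calls (limma, 372 to 435 loci at an unadjusted p under 0.05 against 1285), the splits with 5 calls broke them, and for the slope difference 2 of those 3 gave at least 488 loci.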

How the results depend on the processing

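Settings with single libraries left out, loci of a single symbol, the list settings other than the estimated correlation and the pseudocount, limma on site levels, levels of 0.4 or more and the removal of pre-ribosomal RNA sites were chosen after the data were seen. Over comparisons, 102 of 152 alternative values kept their direction and side of the threshold or stayed within set limits, 43 moved, 3 became stronger, 2 weaker and 2 reversed. The limits included a ratio of 1.5 for counts and 0.00436 for the median difference at shared sites. Some values could not move. The fitted slope equals that of 6 h against 0 h, and the filter on mitochondrial, rRNA and tRNA genes removed no site. Of 1215 values of named genes, 973 stayed, 222 lost and 19 gained the threshold and 1 reversed. Of 209 values of called lists, 152 stayed, 49 lost the call and 8 reversed. Causes were not tested except where a setting uses fewer loci or libraries. Genotype calls (9) became 4 without a filter, 15 at a mean RPKM of at least 5, 3 with quantile normalization and 5 without the trend, and ranged from 0 to 12 with a time or library left out. Time calls (952) became 114 with quantile normalization, 9 at 3 h alone, 580 at 6 h alone and 0 in Tet2 KO alone, and ranged from 0 to 1476 with a library left out. Slope difference calls (0) ranged from 0 to 293, and the median slope difference of 0.02 per h was -0.0104 at 3 h against 0 h. Lists called were 6, 9 and 4 for genotype, time and slope difference and 0 in each with an estimated correlation. With a library left out they ranged from 3 to 5, from 5 to 10 and from 1 to 8, and for the slope difference they were 2 with loci of several symbols and 1 with quantile normalization. The ribosomal list over time reversed with quantile normalization (0.325). With libraries left out the adjusted p of the slope difference ranged from 0.00137 to 0.925 for ribosomal proteins, 0.000336 to 0.925 for oxidative phosphorylation, 6.03e-43 to 5.92e-05 for histones and 1.27e-09 to 0.377 for Zfp genes, and the slope difference of Tet2 (-0.04) from -0.18 to 0.10.

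Sites in wild type, Tet2 KO and both (4128, 4781 and 1039) were 890, 1134 and 415 at 0.2 or more and 146, 215 and 96 at 0.4 or more. The median difference at shared sites (0.002) was 0.00800 at 0.2 or more and ranged from -0.002 to 0.01 with replicates left out, and the share higher in Tet2 KO ranged from 48.9% to 57.5%. The replicate numbers of the genotypes share no stated origin. Across shared sites the deviations of same-numbered replicates correlated at -0.00154, over 2 pairs of numbers, but that correlation cannot show a shift common to all sites. The median of replicate 2 minus replicate 1 was -0.007 in wild type and -0.006 in Tet2 KO, so a shared origin stays open. With the replicate block limma called 0 shared sites, as without it, with 93 against 69 at an unadjusted p under 0.05. Genes with sites of 0.2 or more in both tables moved from percentile 50.4 to 1.47 for level and from 71.7 to 97.7 for slope, and genes of the wild-type table only from 1.82 to 8.38 for level, or 21.8 at a mean RPKM of at least 5. Removing sites in annotated mitochondrial, rRNA and tRNA genes removed none and tests nothing, because the annotation used lists no 45S pre-ribosomal RNA. At such a repeat on chromosome 17, positions 39843517 to 39848789, lay 10 wild-type and 9 Tet2 KO sites, 7 in both, and without them 4118, 4772 and 1032 sites were left and the median difference was 0.002. Not run for lack of coverage or a genome: coverage minimums of 20 and 30, the Cochran-Mantel-Haenszel and quasi-binomial tests, the added minimum difference of 0.1 to a count test, and sequence context with its alternatives. The unknown coverage limits every site level, and the 1 library per genotype and time limits the RNA tests.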

Other observations

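The tests of RNA level behind site listing, of S-phase genes and of X-linked loci were chosen before their results were seen, and the other tests of this part after. Bootstrap intervals in this part resample genes as if independent and hold no error between libraries or cultures. What they argue against is limited to these libraries. The genes and chromosomes of this paragraph were also chosen after their values were seen. Trim71, a regulator of stem cell RNAs and a target of let-7, held the most positions of any gene, 11, of which 2 were in the wild-type table and 10 in the Tet2 KO table. Cdv3 held 10 positions (7 and 5) and Irf2bp2 10 (9 and 3), while Hnrnpul2 held 8 (1 and 8) and Mtf2, a Polycomb partner, 8 (1 and 7). Endoderm genes held 12 wild-type and 3 Tet2 KO sites, imprinted genes 11 and 4, and proteasome genes 4 and 13. The X chromosome held 71 wild-type and 112 Tet2 KO sites, a ratio of 1.58, against 1.16 over the genome. These are counts of listed sites, and depth was unknown in both tables.

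Most m5C sites were listed in 1 genotype's table alone. RNA level as the main cause was set to give a difference of at least 0.1. Genes in the Tet2 KO table only and genes in the wild-type table only differed by 0.0279 in their median log2 RNA difference (bootstrap interval -0.00158 to 0.0619). These medians argue against a general RNA level difference of that size between these groups of genes. They average RNA over the actinomycin D times, in libraries other than the bisulfite ones. They cannot exclude RNA level or coverage as a cause at single sites. Genes of the wild-type table only lay at percentile 1.82 for the level difference (2.37 at 0 h alone), the direction that RNA level would give. Low-level sites falling on either side of the listing minimum may account for part of the listing in 1 table alone. Of wild-type sites of level 0.3 to 0.5, 74.7% were in the other table against 11.1% at 0.1 to 0.15, with intervals apart. A listing minimum would also give such a rise with a difference in level or coverage between the genotypes, so it does not tell these accounts apart. At 0.5 to 1 the share was 73.5% for wild-type sites and 60.9% for Tet2 KO sites. The rest of these were not low-level sites, so falling on either side of the minimum does not cover them. A general rise of m5C with the loss of Tet2 could add sites to the Tet2 KO table, which held 1134 sites against 890 at 0.2 or more and 215 against 146 at 0.4 or more. Of the unequal shared sites 51.8% were higher in Tet2 KO, with an interval from 48.7% to 54.9%. In simulated levels with the replicate spread of these sites, a shift of 0.02 gave 67.1%. The share therefore argues against a general rise of that size at shared sites. A smaller rise stays open, as does a rise at sites in 1 table alone, because a shared site had to reach 0.1 in both genotypes. A difference in coverage between the genotypes, which was not tested, stays open too.

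Histone transcripts were lower in Tet2 KO, with a median log2 difference of -0.96 over 33 genes, averaged over the 3 times. The difference was not constant, since their median slope was -0.54 per h in Tet2 KO and -0.82 in wild type. Fewer cells in S phase, when these genes are expressed, would lower S-phase genes if their RNA follows the share of such cells. Of the S-phase genes 28 were measured, and 23 were higher. Their median, also averaged over the 3 times, was 0.130 (0.0631 to 0.212), above 0. That argues against fewer cells in S phase only as far as this RNA follows their share, which was not tested. Replication-dependent histone mRNAs lack a poly(A) tail, and less carry-over of such RNA through poly(A) selection in the Tet2 KO libraries is a candidate explanation: 218 small structured RNA loci had a median of -0.448 (-0.509 to -0.398). That interval holds -0.480, the histone median divided by 2, which was the limit set for it, so the data leave it open. An effect of the genotype itself was not tested.

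Of 6 Y-linked loci, named after their values were seen, Eif2s3y (-2.04, adjusted p = 0.0685), Uty (-1.21, 0.210), Ddx3y (-0.98, 0.309) and Gapdh-ps15 (-0.25, 0.670) were lower in Tet2 KO and Gm20826 (0.25, 0.695) and Gm20775 (0.27, 0.687) higher, with a median of -0.614 that rests on the first 3, and none passed. Fewer male feeder cells stays open: the 18 fibroblast markers had a median of -0.0919 (-0.129 to 0.0453), above -0.307, the Y-linked median divided by 2, but without 7 that stem cells may also express, among them the most abundant, Vim (0.12) and Fn1 (-0.11), the median was -0.127 (-0.346 to -0.0738), an interval that holds -0.307. Of the other 11, 9 were lower, among them Thy1 with -0.66, Col1a1 with -0.45 and Loxl1 with -0.35, and Prrx1 was higher with 0.45, and none of these 4 passed. A mix with female cells that gains X-linked RNA is argued against by X-linked loci, whose median exceeded that of autosomal loci by 0.0544 (0.0150 to 0.0860), under the 0.2 set for it. Loss of the Y chromosome in part of the cells, and another origin of the knockout clone, stay open and were not tested.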
